A study of Drosophila melanogaster with 2 samples.

How the data were processed

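Chromatin immunoprecipitation followed by sequencing was carried out on whole wandering larvae of the last instar of Drosophila melanogaster, males and females together, from a transgenic line carrying Cnc fused at its C terminus to eGFP. The immunoprecipitation used an antibody against GFP, per the labels. The series held 2 biological replicates of 1 group. Chromatin was sheared by sonication, per the labels. No control sample was part of the samples analysed here, and no second condition was present.

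The data were peak lists in the narrowPeak layout on the genome builds dm6 and dm3, per the deposited file lists. Each replicate had its own list, called on that replicate's alignments against a control, per the deposited file lists. A pooled list was called on the alignments of both replicates together, per the deposited file lists. A list of reproducible peaks, kept by a threshold on the irreproducible discovery rate (IDR), was derived from both replicate lists and a further list not used here, per the deposited file lists. The aligner, the peak caller, their versions and the IDR threshold are not given in the sources used here. The replicate lists and the pooled list held exactly 30000 peaks each, so that their length carries no information on the number of bound sites. The dm3 lists were used only as alternatives. Each reproducible peak on dm6 was present unchanged in the pooled list, and these peaks were its 6153 highest by signal value.

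The height of a peak is the authors' deposited signal value, a peak score made against the control whose scale is not given in the sources used here. The −log10 q value of each peak was also deposited by the authors, and the p-value column was not filled in. Signal values belong to the list they stand in and were used to describe, rank and select peaks within that list. No mean or standard deviation over replicates was therefore formed, and signal values in the text are those of the pooled call unless a replicate is named. For a reproducible peak, the replicate value is the highest signal value among overlapping peaks of that replicate's list. Read numbers per library were not used here, so the sequencing depth is unknown. Exact binomial intervals given for shares of peaks cover counting error over peaks only, and neither peaks nor genes are independent replicates.

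The reproducible dm6 list was the main peak set. Coordinates are 1-based on dm6, and no coordinates were converted between builds. Gene models came from Ensembl release 115, and the genome sequence from the RefSeq assembly of the same chromosomes. Overlap between lists required at least 1 bp and was computed in Python 3.11.15 and checked with bedtools 2.31.1. The replicate signal values were compared with Spearman and Pearson correlations across peaks, with 1000 bootstrap resamples of peaks. Summits were assigned to annotated features and called promoter summits within 1000 bp of an annotated transcription start site (TSS). Their shares were compared, two-sided, with 1000 sets of random positions, with the same number on each chromosome, for which the smallest possible p is 0.001. The distance to a TSS counted in either direction. At a short gene a promoter summit can therefore lie past the 3′ end, as at Grx1, Sgs5bis and Cpr47Ec.

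Motifs were counted in windows of 50 bp either side of the summit, on either strand. Windows centred 1000 bp to either side of the summit served as background. The 13 motifs fixed in advance and all 7-base words were tested with two-sided Fisher exact tests and Benjamini-Hochberg adjustment within each family. Shuffled windows kept the dinucleotide content of each summit window, with 5 copies per window. The 22 gene lists were tested in the same way, comparing members with a promoter summit against the other protein-coding genes among 13945 on 6 nuclear chromosomes. The tRNA list was tested against all other annotated genes of these chromosomes. A circular shift of the peak assignments along the gene order, with 10000 shifts, was run as an alternative because neighbouring genes can share a peak. The symbol phm, an older symbol of more than 1 gene, was taken as phantom (phtm). The names ple1 and Npl in the fat body list matched no gene, and the 32 names of the antioxidant list gave 31 genes. Tests used scipy 1.17.1 and numpy 2.4.6.

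The tests, gene lists and most alternatives were fixed before the data were examined. Genes and peaks were named by a rule fixed at the same time. It takes the 25 reproducible peaks with the highest signal value, each with the gene of the nearest TSS. It always takes cnc, Keap1, maf-S, GstD1, Gclc, Trxr1 and ref(2)P. It takes up to 4 members of each list with the highest promoter peak, and peaks on the mitochondrial genome. A further gene taken by this rule was left out and is not reported here. Alternatives covered the overlap rule, the build, the peak set with each replicate left out, a stricter signal threshold, window widths, the distance to the TSS and the background. Some tests were chosen after seeing the data. Added motif tests used the 500 highest peaks, shuffled windows of 100 bp either side, windows away from the summit, and TGACTCAGC against shuffled windows. An added gene list run used peaks high in both replicates. The P450 list was also run without 2 cyclophilins, and the heat shock list without Hsf. The rank and word tests were also run without each replicate.

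The procedures were tested on simulated data. With the Cnc-Maf motif planted in 1% of 6153 shuffled summit windows, the recovered excess was 1.02 percentage points (exact p = 6.8e-05). With 2% planted it was 1.98 percentage points (exact p = 3.9e-13). The background here was other shuffled windows, so the comparison with flanks of different base composition was not covered. In 20 simulated runs of the gene list test, 60 of 60 planted calls were recovered and 1 of 360 unplanted tests was called. Each gene was drawn independently in these runs, so they do not give the rate of false calls for neighbouring genes that share a peak.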

Results

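Binding of Cnc was mapped in whole wandering larvae of the last instar. Cnc (cap'n'collar) is the fly counterpart of the Nrf2 family of basic leucine zipper (bZIP) factors, which pair with small Maf proteins and are held in check by Keap1. The larvae carried a Cnc-eGFP fusion, and chromatin was precipitated with an anti-GFP antibody in 2 biological replicates of 1 group. The data asked where in the genome the tagged factor was found, which sequences lay under its peaks and which genes had a peak at their promoter. With 1 group and no control sample among those analysed here, no comparison between conditions was made. Read numbers were not used here, so the depth behind each list is unknown.

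The reproducible list held 6153 peaks on dm6, which merged into 5789 regions with a median peak width of 364 bp. They lay on all 6 nuclear chromosomes tested, at 41.2 peaks per Mb on the X and 49.3 per Mb on 2L. Chromosome 4, a small and largely heterochromatic chromosome, stood apart. It had 28.9 reproducible peaks per Mb, but 607 pooled-list peaks per Mb against 174 to 247 on the others. Of its 818 pooled peaks, 39 (4.77%) were in the reproducible list, while on the other chromosomes the share was 19.3% to 23.7%. That list was the 6153 highest pooled peaks by signal value, so this share shows lower signal values on chromosome 4. Overlap between the replicates was not measured per chromosome. The authors' list on dm3 held 7394 reproducible peaks.

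The reproducible list was derived from both replicate lists, so its overlap with them was largely fixed by how it was made. Of the 6153 reproducible peaks, 6085 (98.9%) overlapped a replicate 1 peak, 6069 (98.6%) a replicate 2 peak, and 6003 (97.6%, exact 95% interval 97.1 to 97.9) a peak of both, with an overlap of at least 1 bp. The replicate lists run far below the reproducible threshold. When each was taken only to its highest 6153 peaks, the share in both was 72.7%. Across whole lists, 62.0% of the 29967 nuclear replicate 1 peaks overlapped a replicate 2 peak, against 14.4% on average when they were placed at random. Signal values at the 6003 shared peaks were correlated across peaks, with a Spearman rho of 0.753 (bootstrap 95% interval 0.739 to 0.767) and a Pearson r of 0.796 on the log2 scale. With 1 group, no test between conditions was possible.

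Cnc-eGFP peaks lay mainly at promoters. Of the 6153 summits, 4053 (65.9%, exact 95% interval 64.7 to 67.1) were within 1000 bp of an annotated TSS, against a mean of 23.7% and a highest value of 25.5% in 1000 random sets (2.78-fold, permutation p = 0.001, the smallest possible). Around protein-coding genes the summits sat just upstream. Of 3832 summits within 1000 bp of a protein-coding TSS, 2736 (71.4%) were upstream of it, and the median position was -91 bp. Summits in 5′ UTRs were 3.73-fold more frequent than at random (12.6% against 3.37%). Summits in coding exons were rare, with 37 (0.601%) against 16.8% at random, and 3′ UTRs held 2.16% against 4.92%. Introns held 42.9% of summits against 42.6% at random (permutation p = 0.688). Of the 1230 highest peaks by signal value 75.7% were at promoters, and of the 1231 lowest 61.1%.

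**Figure D1:**
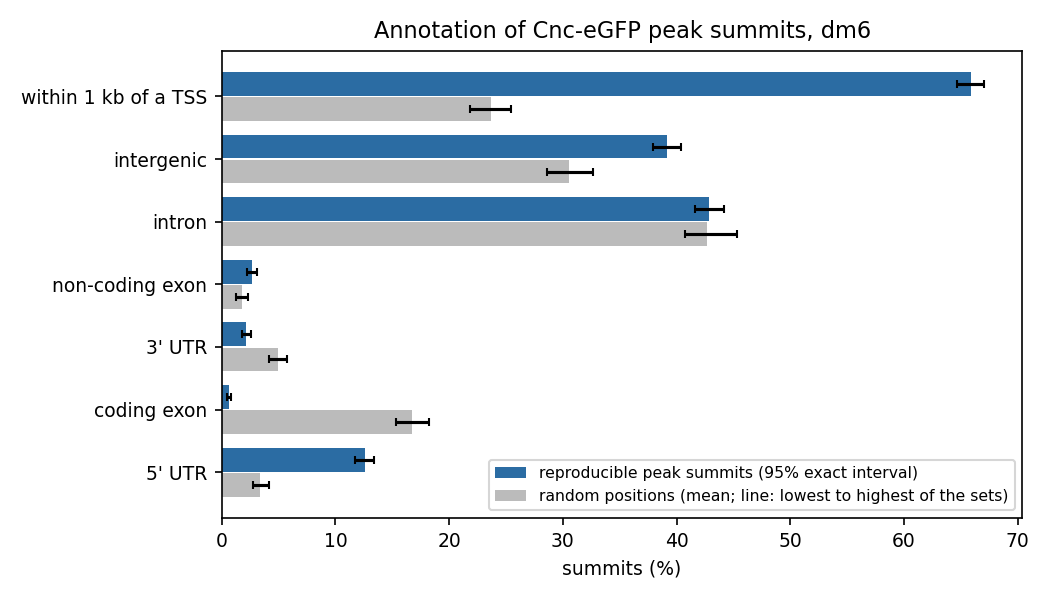
Share of reproducible peak summits (blue, with exact 95% binomial intervals) and of random positions (grey, mean with the range over 1000 sets) within 1000 bp of a TSS and in each annotated feature, in percent of 6153 summits. The feature classes exclude each other, while the promoter class overlaps them, and 65.9% of summits against 23.7% of random positions were at promoters.

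The 25 highest peaks were led by promoters of genes with varied functions. The highest peak (3L, 19590397 to 19590867, signal value 7349) had its summit in intergenic sequence 98 bp from the TSS of CG14100, with signal values of 4310 in replicate 1 and 3096 in replicate 2. The next lay on X (2703680 to 2704112, 7252) within 1000 bp of the TSSs of both Ugalt, a UDP-galactose transporter gene, and eIF2Bbeta, which encodes a translation initiation factor subunit. An intronic peak followed on 2L (6612490 to 6612903, 6786), 1012 bp from the nearest TSS, that of CG11050. Another intronic peak on 2L (480884 to 481290) reached 5945. Its nearest TSS, 1418 bp away, was that of cbt, which encodes the zinc finger factor cabut. The peak near the TSSs of Tcs5 and CHMP2B on 3L reached 5796. A peak in a 5′ UTR on 2R, nearest to the TSS of CG1888, reached 5433. Further down were intronic peaks nearest to the TSSs of ph-p, a Polycomb group gene (4935), and norpA, the phospholipase C of phototransduction (4810). The transcription factor gene Sox14 had an intergenic peak 283 bp from its TSS (4409). Peaks near the mitochondrial ribosomal protein genes mRpL41 (4328) and mRpS10 (3859), near the TSSs of CG8320 and the peroxin gene Pex11ab (4327), and near the chromodomain protein gene Chro (4039) and the small heat shock protein gene Hsp27 (3472) were also in this set. The remaining peaks were nearest to CG16753, CG5611, Atat, CG9663, CG13390, CG7601, LPCAT, CG32772, CG31668, CG8360 and SLC5A11. Of the 25, 19 had a summit within 1000 bp of a TSS, 12 had the TSS of a further protein-coding gene within that distance, 12 summits were intergenic and 9 intronic. None of the 25 summit windows held the Cnc-Maf motif. It lay in 2.73% of all 6153 summit windows, so 25 windows are too few to show a lack.

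The gene cnc (3R, 23185580 to 23226711) contained 20 reproducible summits. Its highest promoter peak (23189869 to 23190296) lay in an intron with a signal value of 2133, and of 1109 and 1053 in replicates 1 and 2. The window of 100000 bp with the most reproducible summits in the genome, 40, overlapped this gene (3R, 23140001 to 23240000). How much of this region the tagged transgene carries is not given in the sources used here. Keap1, the adaptor that targets Cnc-type factors for degradation, had a peak 491 bp downstream of a TSS (3R, 17077581 to 17077700, 793, with 328 and 433 in the replicates). The small Maf gene maf-S had a peak 633 bp downstream of its TSS (2R, 20641427 to 20641790, 250.7). Its summit lay near the 3′ end of this short gene (20640976 to 20641668). Without replicate 2 the maf-S peak fell to rank 6380, outside the 6153 highest. Promoter peaks were also found at GstD1, a glutathione S-transferase gene widely used as a Cnc reporter (3R, 12369632 to 12369995, 294), at the thioredoxin reductase gene Trxr1 (X, 8244367 to 8244730, 249) and at ref(2)P, the fly p62 (2L, 19542335 to 19542698, 353). Gclc, the catalytic subunit of glutamate-cysteine ligase, had no reproducible promoter peak. The nearest reproducible summit was 2620 bp from its TSS, and the nearest pooled-list summit 48 bp.

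**Figure D2:**
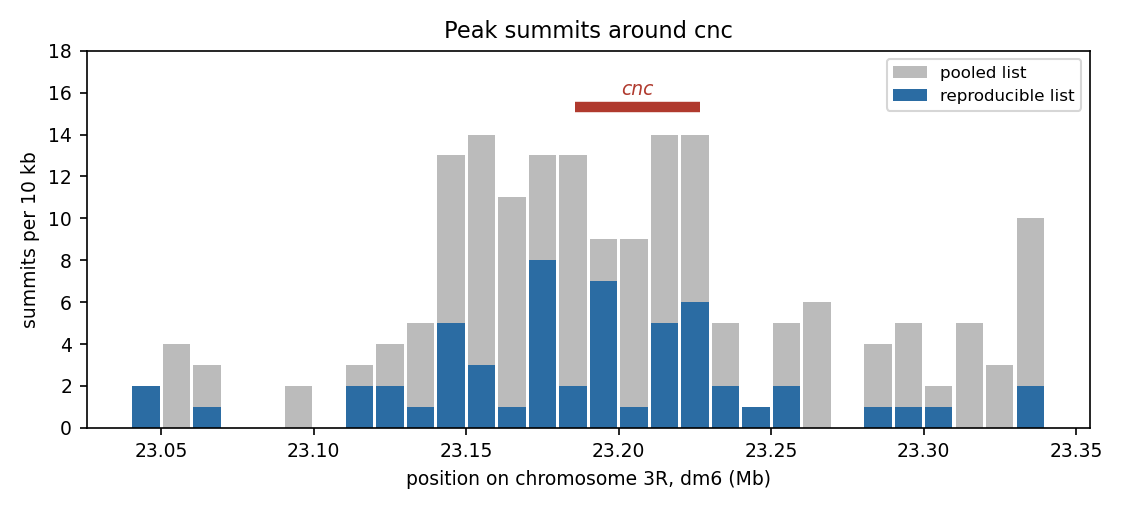
Number of peak summits in each bin of 10000 bp around cnc on chromosome 3R of dm6, in the pooled list (grey) and the reproducible list (blue, drawn in front), by position in Mb, with the extent of cnc as a red bar. The pooled list has 9 to 14 summits in each bin from 23140001 to 23230000, and 0 to 5 in each of the 10 bins before.

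In total, 4449 of 13945 protein-coding genes (31.9%) had a reproducible summit within 1000 bp of a TSS. Any annotated TSS of a gene counted, so genes with many TSSs, such as cnc with 10, covered more sequence. Neither the exact test nor the circular shift adjusted for the number of TSSs per gene. Of 22 gene lists, 10 differed from other genes, 6 upward and 4 downward, and the circular shift also called 6 upward and 4 downward. Proteasome genes had the highest share, with 29 of 34 (85.3%, odds ratio 12.5, 95% interval 4.82 to 32.2, adjusted exact p = 9.4e-10 by two-sided Fisher exact test). Rpn6 (1381), Rpn2 (1216), Rpn13 (1161) and Prosbeta3 (1053) had the highest signal values among them. Autophagy genes followed with 16 of 21 (76.2%, odds ratio 6.85, adjusted exact p = 0.000123), led by Atg17 (1727), Atg18a (1631), Atg12 (1194) and Atg2 (1158). Of the bZIP factors and Cnc partners, 14 of 19 had a peak (73.7%, odds ratio 5.99, adjusted exact p = 0.000617), with the stress response factors Atf3 (2021) and Xbp1 (1902) and Irbp18 (1237) after cnc. Without replicate 2 the odds ratio of this list was 3.63, and its call was lost in the upper part of the peaks by signal value (2.29, adjusted exact p = 0.158). That of autophagy genes was 4.42 without replicate 1 and 2.94 in the upper part (adjusted exact p = 0.0488).

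Antioxidant and NADPH-producing enzymes had a promoter peak in 17 of 31 cases (54.8%, odds ratio 2.60, 95% interval 1.28 to 5.27, adjusted exact p = 0.0234). The highest were Sesn (1306), the mitochondrial superoxide dismutase gene Sod2 (1231), Gclm, the modifier subunit of glutamate-cysteine ligase (627), and Grx1 (533). The Grx1 summit lay 874 bp downstream of a TSS, past the 3′ end of the gene. Without replicate 1 the odds ratio was 4.02. The detoxification families did not pass the test. Glutathione S-transferases had a peak in 10 of 36 cases (27.8%, odds ratio 0.821, adjusted exact p = 0.721), with GstE13 (3380) far above GstO3 (534), GstE3 (424) and Mgstl (354). The list of cytochrome P450 genes, taken by symbol, also held the cyclophilin genes Cyp1 and Cyp40 and had a peak in 19 of 85 cases (22.4%, adjusted exact p = 0.0972), led by Cyp6u1 (2023), Cyp310a1 (647), Cyp6d5 (597) and Cyp6a2 (531). Without replicate 2 the odds ratio of this list, 0.613, became 0.489 and passed the test. Without the 2 cyclophilins 18 of 83 had a peak (odds ratio 0.589, adjusted exact p = 0.0826), and without replicate 2 as well the odds ratio was 0.465 and passed the test. UDP-glycosyltransferases had a peak in 5 of 35 cases (14.3%, adjusted exact p = 0.056), with Ugt316A1 (435) highest, followed by Ugt302E1 and Ugt302K1, which shared a peak (234), and Ugt35C1 (219.8). For UDP-glycosyltransferases the odds ratio was 0.355, and it passed the test without replicate 1 (0.133) and without replicate 2 (0.352). The exact test counts neighbouring genes that share a peak separately. By the circular shift on the main peak set, adjusted p was 0.150 for UDP-glycosyltransferases and 0.210 for the P450 list. The peak of Ugt35C1 fell outside the 6153 highest without replicate 1 (rank 7297) and without replicate 2 (7300), and that of Ugt302E1 and Ugt302K1 without replicate 1 (6656).

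Cytosolic ribosomal protein genes had a peak in 55 of 92 cases (59.8%, odds ratio 3.20, adjusted exact p = 2.3e-07), among them RpL32 (2445), RpL34b (1665) and RpS20 (1436). With the nearest TSS at any distance the odds ratio was 1.76 (adjusted exact p = 0.0195). Nuclear genes of the mitochondrial respiratory chain had a peak in 37 of 88 cases (42.0%, odds ratio 1.55, adjusted exact p = 0.0924), led by Cyt-c-p (1631), ND-SGDH (1175), ND-42 (1161) and ND-24 (1146). This list passed the test without replicate 1 (odds ratio 1.68). The list of heat shock protein genes, which included the heat shock transcription factor gene Hsf, had a peak in 11 of 24 cases (45.8%, adjusted exact p = 0.228), with Hsp27, Hsc70-5 (1254), Hsp26 (713) and Hsc70-4 (538), and passed the test without replicate 2 (odds ratio 2.5 against 1.81). Without Hsf 10 of 23 had a peak (odds ratio 1.64, adjusted exact p = 0.306), and the list then did not pass without replicate 2 either (2.31, adjusted exact p = 0.0768).

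Fat body genes had a peak in 11 of 17 cases (64.7%, odds ratio 3.92, adjusted exact p = 0.017), including the lipase gene bmm (754), Desat1 (495), Lsp1gamma (365) and Adh (354). This call rested on both replicates, since without replicate 1 the odds ratio was 1.54 and without replicate 2 it was 2.38, neither past the threshold. Midgut digestive enzyme genes had a peak in 1 of 45 cases (Mal-A5, 1107, adjusted exact p = 3.8e-06), cuticle protein genes in 4 of 122 (adjusted exact p = 2.0e-14; Cpr72Eb 464, Lcp1 303, Cpr73D 277 and Cpr47Ec 217) and chemosensory receptor genes in 3 of 179 (adjusted exact p = 2.4e-24; Ir60e 529.9, Gr32a 321 and Ir31a 236). The lists of muscle genes (5 of 24; Msp300 873, Actn 541 at the same peak as usp, Tm1 489 and sls 278), glue genes (4 of 22; Sgs1 535, Sgs5 and Sgs5bis sharing a peak at 497, and Eig71Ee 214) and neuron and glia genes (3 of 23; elav 1054, moody 781 and Syx1A 561) did not pass the test (adjusted exact p = 0.309, 0.291 and 0.104). With a replicate left out, all 3 called lists stayed past the threshold. The odds ratio of midgut genes, 0.0483, became 0.102 without replicate 1 and 0.151 without replicate 2, and without replicate 2 those of cuticle genes (0.0715) and chemosensory genes (0.0357) became 0.0348 and 0.0117. Outside the 6153 highest fell the peaks of sls (rank 8431), Eig71Ee (17037) and Cpr47Ec (7006) without replicate 1, and of Lcp1 (9597), Cpr73D (6530), Gr32a (8149) and Ir31a (8128) without replicate 2. Cpr47Ec had no overlapping peak in the replicate 1 list, so it was also lost without replicate 2.

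Among regulators of molting, ecdysone response factors had a peak in 8 of 16 cases (50%, odds ratio 2.14, adjusted exact p = 0.228). Eip75B (1098), tai (573), usp (541) and Hr3 (394) were the highest. Without replicate 1 the odds ratio was 3.68 and passed the test. Ecdysone synthesis genes had a peak in 2 of 12 cases, Npc1a (470.2) and shd (216) (adjusted exact p = 0.377). The Npc1a peak was also that of the proteasome gene Prosalpha6. The shd peak had rank 6845 without replicate 1 and 9949 without replicate 2, both outside the 6153 highest. None of the 8 homeotic genes had a promoter peak (adjusted exact p = 0.0972). None of the 111 replication-dependent histone genes had a promoter peak (adjusted exact p = 3.8e-18, adjusted p = 0.0022 by the circular shift). These genes are a repeated array, and the exact test counts its copies as separate genes, which overstates the evidence. How reads that match several places were treated is not given in the sources used here. Of 290 tRNA genes, 67 had a summit within 1000 bp (23.1% against 27.8% of other genes, adjusted exact p = 0.117). The tRNA odds ratio of 0.780 became 0.678 without replicate 1 and 0.507 without replicate 2, and both passed the exact test. That test counts neighbouring genes that share a peak separately, and the 67 tRNA genes had 41 distinct peaks. By the circular shift on the main peak set, adjusted p for tRNA genes was 0.264.

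**Figure D3:**
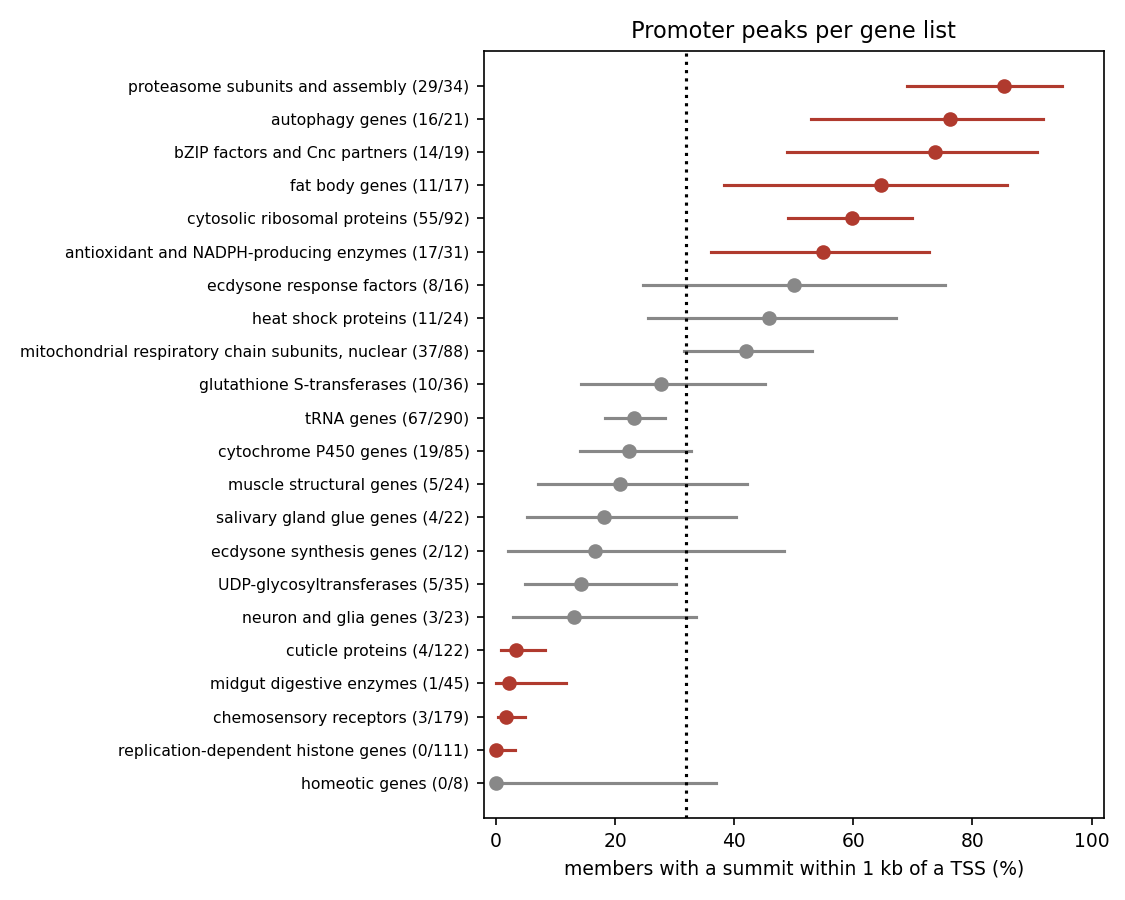
Percent of members of each gene list with a reproducible peak summit within 1000 bp of a TSS (points) with exact 95% binomial intervals, which cover counting error over genes only. Red lists passed an adjusted p of 0.05, and the dotted line marks the 31.9% of all protein-coding genes. Proteasome genes were highest at 85.3%.

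The textbook Cnc-Maf site was rare under the peaks and less frequent there than in flanking sequence. The motif TGACNNNGC occurred in 168 of 6153 summit windows (2.73%) and in 411 of 12306 flanking windows (3.34%), an odds ratio of 0.812 (95% interval 0.677 to 0.975, exact p = 0.0251, adjusted exact p = 0.0408). Against dinucleotide-shuffled summit windows, which held it in 2.21% of cases, the direction turned and the odds ratio was 1.24 (95% interval 1.05 to 1.47, exact p = 0.0154). The lower share against flanks was also no longer past the threshold without replicate 1 (odds ratio 0.840) and without replicate 2 (0.895). Summit windows had 34.4% G and C against 43.2% in the flanks. A stricter form of the Cnc-Maf motif, TGACTCAGC or its reverse complement, lay in 6 summit windows against 8 flanking windows (odds ratio 1.5, exact p = 0.571). Against 7 of 30765 shuffled windows its odds ratio was 4.29 (95% interval 1.44 to 12.8, exact p = 0.0126). Among the 1230 highest peaks 1.63% of windows held the Cnc-Maf motif and among the 1230 lowest 3.17% (odds ratio 0.505, 95% interval 0.293 to 0.870, exact p = 0.017), a difference lost without replicate 1 (0.713, exact p = 0.275) and between upper and lower parts of equal size (0.907, exact p = 0.584). The share did not rise steadily down the list, since the 1231 peaks after the highest 1230 had 3.82%.

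The 6 summits with TGACTCAGC or its reverse complement were chosen after their values were seen. The highest lay in an intron on X (19668433 to 19668794, 3313), with GCTGAGTCA at 19668565 to 19668573, 853 bp from the TSS of asRNA:CR44512 and within the bounds of Zw (19667252 to 19672353), which encodes glucose-6-phosphate dehydrogenase. The others were nearest to AOX3, an aldehyde oxidase gene (3R, site at 15548028 to 15548036, peak 772), CG12290 (3R, 26228258 to 26228266, 658), the NAD kinase gene Nadk1a (2R, 13539978 to 13539986, 349), Tim17a2 (3R, 5262314 to 5262322, 262) and MESR3 (2L, 18622101 to 18622109, 217).

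The DNA replication-related element (DRE) TATCGATA, a core promoter motif of housekeeping genes, lay in 166 summit windows (2.70%) against 0.406% of flanks (odds ratio 6.80, 95% interval 4.95 to 9.34, adjusted exact p = 9.3e-39). Core promoter motif 1 had an odds ratio of 4.70 (adjusted exact p = 2.9e-09), which was 7.93 without replicate 1 and 19.0 against shuffled windows, where the DRE had 17.4. The odds ratio of TATAAA was 2.09 (adjusted exact p = 4.3e-67), not past the threshold against shuffled windows (1.07, exact p = 0.0649). Neither background was matched for distance to a TSS, while 65.9% of summits were within 1000 bp of one. An excess of core promoter motifs can therefore come from the place of the peaks at promoters alone. These tests do not separate it from a sequence preference of the factor. The E-boxes CACGTG (0.585, adjusted exact p = 0.00223) and CAGCTG (0.812, adjusted exact p = 0.0122), the nuclear receptor site AGGTCA (0.694, adjusted exact p = 0.00241) and GAGAGAG (0.764, adjusted exact p = 0.0408) were below the flanks. The CAGCTG and GAGAGAG results turned to odds ratios of 3.45 and 3.93 against shuffled windows. The CAGCTG call was also lost without replicate 1 (0.873) and replicate 2 (0.893), that of AGGTCA in the upper part of the peaks by signal value (0.724, exact p = 0.0524), and that of GAGAGAG without replicate 1 (0.822) and replicate 2 (1.08, turned). AP-1, CRE, Zelda, ACGTGT and heat shock elements did not pass the test (adjusted exact p = 0.684, 0.691, 0.198, 0.684 and 0.337). ACGTGT passed it downward against shuffled windows (0.806, adjusted exact p = 0.017) and in the upper part of the peaks by signal value (0.692, exact p = 0.0163), against 1.05 over the flanks. Of 8192 words of 7 bases, 1255 were more frequent at summits and 2742 less frequent. The 10 with the lowest p were ATCGATA, part of the DRE (5.80% against 1.20%, odds ratio 5.06), and 9 words of A and T, led by TTTAAAA (13.6% against 5.18%, odds ratio 2.88) and followed by AAAAATA, AAAATAA, AAATAAT, TAAAATA, ATTTTAA, TTAAAAA, AAATATA and AAATAAA. Against shuffled windows 751 words were more frequent and 808 less frequent, and ATCGATA had the lowest p of those more frequent (odds ratio 6.23). The 9 words of A and T then had odds ratios of 1.01 to 1.71, with TTTAAAA at 1.23, and TTAAAAA was no longer past the threshold (1.01, exact p = 0.840).

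**Figure D4:**
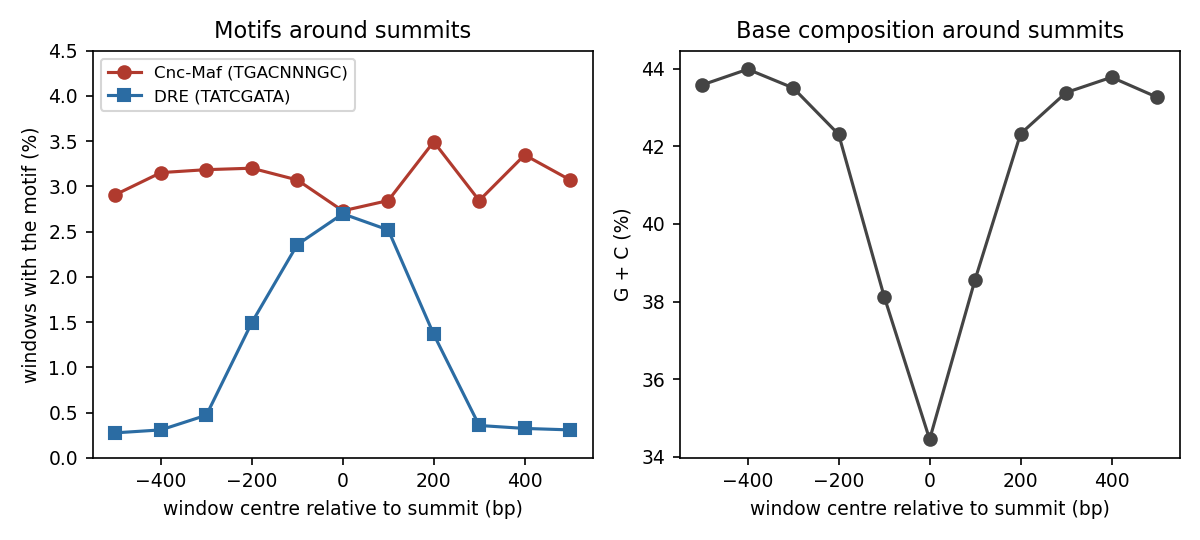
Left, percent of windows reaching 50 bp either side of their centre that hold the Cnc-Maf motif (red) or the DRE (blue), by distance of the window centre from the summit in bp. Right, percent of G and C in the same windows. The DRE rises to 2.70% at the summit, while the Cnc-Maf motif stays between 2.73% and 3.49%, and G and C falls to 34.4%.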

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

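Peaks were listed in data outside the comparisons above. The replicate 1 list on dm6 held 33 peaks on the mitochondrial genome, a molecule of 19524 bp. The highest (1699 to 2219) had a signal value of 5249, above the highest nuclear peak of that list at 4540. The replicate 1 list on dm3, and the replicate 2, pooled and reproducible lists on either build, held 0 such peaks. Whether the mitochondrial genome was left out when those lists were made is not given in the sources used here, so the 0 does not show a lack of signal.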

How the results depend on the processing

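No paired analysis was possible because the series has 1 group. Chosen after seeing the data were the list of peaks high in both replicates, the 500 highest peaks, shuffled windows of 100 bp either side, TGACTCAGC against shuffled windows, the P450 list without 2 cyclophilins, the heat shock list without Hsf, and the rank and word tests without each replicate. Of 225 alternative values for the planned results, 178 kept their direction and side of the threshold or stayed within the limits set, 12 lost and 21 gained a call, 8 turned and 6 moved. Of 285 for single motifs, words and named peaks, 253 kept their direction and side of the threshold or stayed within the limits set, 6 lost a call, 12 turned, and 14 moved, all of them peaks outside the 6153 highest without a replicate. Taking the pooled list to the same number of peaks returned the reproducible list itself, tests nothing and is left out of these counts. The cause of a change was not tested unless stated. The share of peaks in both replicate lists was 72.9% with reciprocal overlap of 50%, 85.8% with summits within 100 bp, 96.6% on dm3 and 72.7% with equally long lists. The replicate correlation was 0.725 over all pooled peaks found in both lists. The promoter excess was 2.79 to 2.83-fold with a replicate left out.

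The Cnc-Maf odds ratio was 0.840 to 0.895 with a replicate left out, 0.656 within 25 bp and 0.889 within 100 bp of the summit. It was 0.752 in the upper part by signal, 0.908 away from TSSs, 1.24 against shuffled windows and 1.5 for TGACTCAGC. The values within 25 bp and in the upper part stayed past the threshold (exact p = 0.00386 and 0.0317). Against shuffled windows the odds ratio was 1.18 for 100 bp either side, 0.869 for the 500 highest peaks at that width and 4.29 for TGACTCAGC. By signal rank it was 0.907 between upper and lower parts of equal size, 3.0 for TGACTCAGC and 0.480 to 0.713 with a replicate left out. Against shuffled windows 751 words were called as more frequent, and odds ratios turned for AP-1 (1.08), CRE (1.60), GAGAGAG (3.93), ACGTGT (0.806), the heat shock element (0.944) and CAGCTG (3.45). ACGTGT also turned in the upper part by signal (0.692), and both turned ACGTGT values passed the threshold. With a replicate left out, AP-1 was at 1.01 to 1.09, CRE at 0.947 to 1.16, GAGAGAG at 0.822 to 1.08 and the heat shock element at 0.914 to 1.13.

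Among gene lists, odds ratios with a replicate left out were 0.489 to 0.590 for P450 genes (0.465 without replicate 2 and the cyclophilins), 0.133 to 0.352 for UDP-glycosyltransferases, 2.72 to 3.68 for ecdysone response factors, 1.87 to 2.5 for heat shock proteins, 1.40 to 1.68 for the respiratory chain, 1.54 to 2.38 for fat body genes and 0.507 to 0.678 for tRNA genes. In the upper part by signal they were 2.29 for bZIP factors, 0.296 for P450 genes, 0.115 for UDP-glycosyltransferases, 1.21 for fat body genes and 0.508 for tRNA genes. Within 500 bp of a TSS they were 0.539 for P450 genes, 0.325 for UDP-glycosyltransferases and 0.558 for tRNA genes. Within 2000 bp they were 1.09 for glutathione S-transferases, 0.353 for UDP-glycosyltransferases and 1.13 for tRNA genes. With the nearest TSS at any distance they were 7.85 for ecdysone response factors, 1.57 for homeotic genes and 0.701 for tRNA genes. With peaks high in both replicates they were 0.388 for P450 genes, 0.0857 for UDP-glycosyltransferases, 1.60 for fat body genes and 0.468 for tRNA genes. Read depth is unknown, so an absent peak does not show absence of binding.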

Other observations

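Tests chosen only after the result was seen were those of further gene groups, divergent promoters, windows away from the summit, the 500 highest peaks, broadly used genes and distal summits around cnc, while the shuffled windows were planned and only their reading as a test of composition came after their value.

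Further gene groups, tested as a family of 13, had promoter peaks at different rates. Mitochondrial ribosomal protein genes had a peak in 46 of 73 cases (63.0%, odds ratio 3.66, adjusted exact p = 6.2e-07), led by mRpL41 (4328), mRpS10 (3859), mRpL23 (3375) and mRpS23 (2752). Genes named as Rab GTPases or their partners had a peak in 19 of 31 cases (odds ratio 3.39, adjusted exact p = 0.00256), peroxins in 10 of 15 (4.28, adjusted exact p = 0.0197) and chaperonin subunits in 6 of 8 (6.41, adjusted exact p = 0.029). By the circular shift, before adjustment over the 13 groups, p was 0.0016, 0.0156 and 0.0312 for these. Aminoacyl-tRNA synthetases (14 of 32), vacuolar ATPase subunits (13 of 33), translation initiation factors (19 of 44), COP9 signalosome subunits (4 of 8) and serpins (7 of 27) did not pass the test (adjusted exact p = 0.237, 0.384, 0.207, 0.326 and 0.68). Odorant-binding protein genes had a peak in 1 of 51 cases (Obp83g, 379.7, adjusted exact p = 9.9e-07), and antimicrobial peptide genes (0 of 20, adjusted exact p = 0.00256) and Osiris genes (0 of 25, adjusted exact p = 0.000485) in none. The unadjusted circular shift p was 0.007 for antimicrobial peptide genes and 0.0156 for Osiris genes. The 10 nicotinic acetylcholine receptor genes had none either (adjusted exact p = 0.0595).

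Promoter summits often lay between genes transcribed away from each other. Of 3832 summits within 1000 bp of a protein-coding TSS, 1306 (34.1%) lay between divergent TSSs, against a mean of 22.5% and a highest value of 24.0% in 200 draws of random TSSs with the same distances (1.52-fold, permutation p = 0.005, the smallest possible). The share of windows with the DRE was 1.95% among the 1230 highest peaks, 2.92%, 3.66% and 2.92% in the groups of nearly the same size that followed by signal, and 2.03% among the 1231 lowest.

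The series has 1 group, so no biological explanation given by a group was tested for the 3 patterns that follow.

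The Cnc-Maf motif was not in excess at summits over flanks, for which a candidate explanation is the AT-rich composition of summit windows, since against shuffled windows the odds ratio was 1.24 (95% interval 1.05 to 1.47, 2.73% against 2.21% of windows). A site lying away from the called summit is argued against by 4 windows centred 100 or 200 bp from it, whose highest odds ratio against their own shuffled copies was 0.988 (0.843 to 1.16), although an excess up to that upper limit is not excluded. Dilution of strong sites by weak peaks stays open, since within 100 bp the 500 highest peaks had an odds ratio of 0.869 against shuffled windows (0.522 to 1.45), an interval that holds the 1.18 of all peaks. The odds ratios of these 500 peaks against their flanks, 0.528 (0.310 to 0.900), and of the 1230 highest against the 1230 lowest peaks at this width, 0.614 (0.428 to 0.879), go against dilution, but neither comparison matched base composition. Signal at open promoters that does not need the factor's own site stays open, because no control immunoprecipitation was analysed here.

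Proteasome genes had promoter peaks more often than other genes. Of them 85.3% had a peak, against 54.5% of 253 ribosomal, respiratory chain and mitochondrial ribosomal protein genes (odds ratio 4.83, 95% interval 1.81 to 12.9, exact p = 0.000659). The ribosomal and respiratory chain genes were taken by symbol, with paralogs such as RpS19b and Cyt-c-d. How broadly each gene is used was not measured. The excess over these sets therefore does not decide on a general preference for broadly used genes. Peaks shared with neighbouring promoters do not account for all of the excess over other genes, since the odds ratio stratified by the number of neighbouring TSSs was 7.27 (3.02 to 17.5). Whether these peaks carry the Cnc-Maf motif more often could not be decided, with 3 of 29 peaks against 5.59% of other promoter peaks (odds ratio 1.95, 0.584 to 6.51).

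Peaks were dense around cnc itself. Among 13331 windows of 100000 bp, the window at 23140001 to 23240000 on 3R, which overlaps cnc, held the most reproducible summits, 40 against a median of 4 and 29 in the next window apart from it. Many promoters in the region are argued against, since 24 of the 40 summits lay further than 1000 bp from any TSS (odds ratio 2.92, 95% interval 1.55 to 5.50, against the rest of the genome). A high share of such summits was not particular to cnc, since the next window had 22 of 29. Extra copies of the region carried by the tagged transgene may raise its signal against the control, and would also raise it in coding exons. Of 115 pooled summits there, 8 were in coding exons (6.96% against 4.44% elsewhere, odds ratio 1.61, 0.783 to 3.31), so this explanation stays open.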
